A study of Mus musculus with 15 samples.

How the data were processed

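Total RNA from mouse cornea was profiled in 15 libraries, 4 from OPA1+/+ animals at 3 months, 4 from OPA1+/- animals at 3 months, 3 from OPA1+/+ animals at 6 months and 4 from OPA1+/- animals at 6 months. Groups, ages and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with Trizol and column purification, ribosomal RNA was depleted, strand-specific libraries were prepared with a directional kit, and single reads of 75 bases were sequenced on a NextSeq instrument. No label gives the sex, litter, number of animals per library, time of day of dissection or batch. The p-values therefore measure the spread between these libraries, and the labels do not say whether each came from separate animals.

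The deposited values are whole-number read counts per gene. Per the file headers, the authors counted reads with featureCounts 2.0.1 on exons summed by gene identifier, with the reverse-strand setting 2 and the GENCODE mouse annotation release 28, and the command has no option that counts reads mapping to several places. The submitters' processing notes name the build mm10 and the tool DESeq2, whereas annotation release 28 is on GRCm39. Of 52044 nuclear gene identifiers shared with annotation release 21, which is on GRCm38, 2.8% had the same start and end. Opa1 starts at base 29398152 in the files and at base 29579334 in release 21. Coordinates given here are those of the files, 1-based, and were read as GRCm39. The aligner is not given in the sources used here. Gene symbols came from a table of identifiers and symbols, used for names alone, which matched 52081 of 55357 identifiers (94.1%). Identifiers without a symbol held 1.07% to 1.87% of the counts of a library, and no row lacked a gene.

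Libraries held 11673240 to 18194946 counts. The limit that a count of 0 allows was set at 3 counts, which was 0.165 to 0.257 CPM. Limits and intervals of this kind cover counting error alone, since the reads carry no molecular identifiers. CPM values are counts divided by the library total and scaled to 1e6, with the total adjusted by trimmed-mean (TMM) factors, except where raw CPM is stated. Genes were kept by filterByExpr on the 4 groups, which left 15770 genes. One edgeR quasi-likelihood model (edgeR 4.0.16, R 4.3.3, robust dispersion and quasi-dispersion) with 1 mean per group was fitted to all 15 libraries, leaving 11 residual degrees of freedom and a biological coefficient of variation of 0.0884. Genotype was tested at each age and averaged over both ages, age was tested in each genotype, and the interaction tested whether the genotype effect differed between ages. Positive genotype values mean higher in OPA1+/-, and positive age values mean higher at 6 months. Adjusted p-values are Benjamini-Hochberg values of edgeR's quasi-likelihood test over all tested genes, with a threshold of 0.05. The error after a log2 fold change is the absolute fold change divided by the square root of the F statistic, and errors after CPM values are SD.

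A collection of 48 gene lists (1160 genes, 841 of them tested) was fixed before the data were examined, from textbook knowledge of cornea, mitochondria and tissues that a dissected cornea could include. The 44 lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists of a contrast. The camera test was repeated with an estimated correlation, and fry tested whether the genes of a list moved on balance in 1 direction. List scores are means over members of log2 CPM minus the gene's mean over the 15 libraries. Named genes followed a rule fixed before the data were examined. It takes Opa1, up to 10 risers and 10 fallers by fold change among genes past the threshold with a mean of at least 1 CPM and a symbol that is not a placeholder. It adds up to 4 members with the smallest adjusted p of each called list and of the mitochondrial, nerve, Schwann cell, neurotrophin and corneal epithelium lists. Where fewer than 5 genes passed, it takes the 10 with the smallest p, and for the interaction also the 5 rising and 5 falling genes with the smallest p among those that pass. Genes named outside the rule are marked as chosen after their values were seen. Opa1 was also tested at each age with an exact two-sided permutation test on log2 CPM.

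Alternatives fixed before the data were examined were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter on low counts, a filter on a mean of at least 1 CPM, the replicate number as a block, a fit of the 2 groups compared alone, limma voom with sample weights, a covariate for summed Y-linked transcripts, a fold change minimum of 1 on the log2 scale, and each library left out in turn. A pair of covariates for clock genes, a covariate for conjunctival transcripts and a fit without the 2 libraries with retina transcripts were added after seeing the data.

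The edgeR procedure was tested on simulated counts for 15770 genes drawn from the measured means, dispersions and library sizes, with 200 genes changed. For the genotype comparison at 3 months it recovered 81.8% of genes changed 2-fold, 55.2% of those changed 1.5-fold and 20.9% of those changed 1.25-fold. At 6 months these shares were 78.8%, 58.2% and 16.4%, and 4.67% of its calls were false. For the comparison averaged over both ages they were 89.4%, 68.7% and 59.7%, and 8.23% of its calls were false. For the interaction, with genes changed at 6 months alone, they were 66.7%, 46.3% and 1.5%. Genes were drawn independently, so differences between libraries that many genes share were not simulated. The shares of recovered and false calls therefore hold for that setting and can differ in these libraries. In a separate simulation, also with genes drawn independently, camera called a list of 20 genes raised 1.25-fold. In it, 1 of the remaining unchanged lists was also called. That simulation does not test the preset correlation for lists whose genes move together. Libraries of a group were compared pairwise for repeated deposition. The chi-square per gene of the 21 pairs was 3.18 to 9.68, above the value of 1 that resampling of a single library would give, and no library was counted as a repeat. Figures were drawn with matplotlib.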

Results

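Corneas of mice carrying 1 disrupted copy of Opa1 (OPA1+/-) and of OPA1+/+ mice were profiled by RNA sequencing at 3 and 6 months. Opa1 encodes a dynamin-related GTPase of the inner mitochondrial membrane that acts in membrane fusion and in the shaping of cristae. The series title places the study in the context of inherited mitochondrial dysfunction and of the sensory nerve fibres of the cornea. There were 4 libraries of OPA1+/+ and 4 of OPA1+/- corneas at 3 months, and 3 and 4 at 6 months. Totals ran from 11673240 counts (OPA1+/+ at 3 months, replicate 1) to 18194946 counts (OPA1+/- at 3 months, replicate 4), and 22196 to 23886 genes had at least 1 count. Krt12, the keratin of differentiated corneal epithelium, was at 26397 to 32902 raw CPM in the 15 libraries. Each library held both Xist, the RNA of the inactive X chromosome (1433 to 1969 raw CPM), and transcripts of 4 Y-linked genes (126 to 172 raw CPM summed), so every library contained RNA of both sexes.

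Opa1 was lower in OPA1+/- corneas at both ages. At 3 months it was at 67.8 ± 2.34 CPM in OPA1+/+ (SD, n = 4) and at 50.9 ± 5.07 CPM in OPA1+/- (n = 4), a log2 fold change of -0.41 ± 0.06 (adjusted p = 0.0193). At 6 months it was at 69.3 ± 3.59 CPM (n = 3) and 47.9 ± 1.06 CPM (n = 4), a log2 fold change of -0.53 ± 0.06 (adjusted p = 0.000623). Averaged over both ages it fell by 27.9% (log2 fold change -0.47 ± 0.04, adjusted p = 1.83e-05). The 8 OPA1+/- libraries lay at 45.5 to 57.8 CPM, below the 65.2 to 73.4 CPM of the 7 OPA1+/+ libraries. The gene lies on chromosome 16 from base 29398152 to 29473702 on the plus strand (GRCm39). An exact two-sided permutation test gave p = 0.0286 at 3 months and p = 0.0571 at 6 months, in each case the smallest p that the library numbers allow. Neither the age difference of Opa1 in OPA1+/+ (log2 fold change 0.03 ± 0.06, adjusted p = 0.912) nor that in OPA1+/- (-0.09 ± 0.06, adjusted p = 0.699) passed. At 3 months the edgeR call was lost without OPA1+/+ replicate 1 (adjusted p = 0.113) or replicate 3 (0.0516), or without OPA1+/- replicate 2 (0.0629), 3 (0.103) or 4 (0.0586), while the fold change stayed between -0.49 and -0.36. It was also lost with the replicate block (0.0515), the Y-linked (0.0939) or clock covariates (0.19) and only the 2 groups compared (0.0578). The fit without the 2 libraries with retina transcripts ended it too (0.0512).

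**Figure D1:**
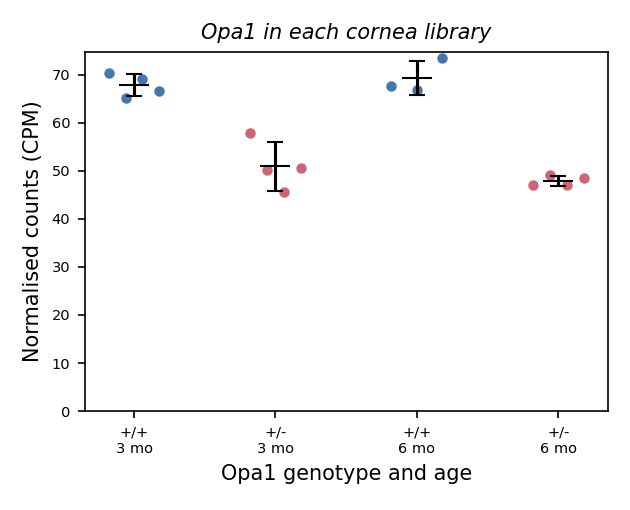
Opa1 in CPM (vertical axis, linear from 0) in each library, by genotype and age (horizontal axis). Points are libraries, horizontal marks are means and bars are SD, and the OPA1+/- libraries lie between 45.5 and 57.8 CPM and the OPA1+/+ libraries between 65.2 and 73.4 CPM.

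The first comparison asked which genes differed between the genotypes at 3 months. Opa1 was the 1 gene that changed at this age. Genes with the next smallest p did not pass. Slc16a3, a lactate transporter, was at 1.23 ± 0.38 CPM in OPA1+/+ and 3.27 ± 0.34 CPM in OPA1+/- (log2 fold change 1.41 ± 0.26, adjusted p = 0.0755). Dusp3, a phosphatase of MAP kinases, had 0.42 ± 0.08 (adjusted p = 0.0755). Rai1, a chromatin regulator of clock gene transcription, had 0.35 ± 0.06 (adjusted p = 0.0707), and the mitochondrial ribosomal RNA mt-Rnr2 had -0.24 ± 0.04 (adjusted p = 0.0755). Kitl, the ligand of the Kit receptor, had -0.35 ± 0.07 and Itga3, an integrin of epithelial basal cells, 0.30 ± 0.06, both with an adjusted p of 0.128.

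Among the lists at 3 months, glycolysis genes were higher in OPA1+/-: 18 of 20 measured members had positive fold changes, with a median log2 fold change of 0.15. None passed over all genes and 6 were higher when adjusted over the list alone. The list had adjusted p = 2.84e-07 with camera's preset correlation and adjusted p = 0.303 with an estimated correlation. Besides Slc16a3, examples were the glycolytic enzymes Pgam1 (0.40 ± 0.13) and Hk1 (0.20 ± 0.07). Cell cycle genes were lower, with 28 of 35 members negative, a median of -0.24, none passing over all genes and 1 lower when adjusted over the list alone (adjusted p = 3.98e-06, and adjusted p = 0.573 with an estimated correlation). The scores overlapped, at -0.192 to 0.347 in OPA1+/+ and -0.259 to 0.06 in OPA1+/-, and the call was lost without OPA1+/+ replicate 3 (adjusted p = 0.059). Kif11, a mitotic kinesin, had -0.44 ± 0.11 and Nusap1, a spindle protein, -0.49 ± 0.14. Basement membrane genes were higher, with 18 of 25 members positive and a median of 0.07, and 5 were higher and 1 lower when adjusted over the list alone (adjusted p = 0.00835, and adjusted p = 0.303 with an estimated correlation). The call was lost without OPA1+/- replicate 1 (adjusted p = 0.0666). In the same libraries the score of 14 corneal endothelium markers was -0.129 to -0.045 in OPA1+/+ and 0.057 to 0.108 in OPA1+/- (list adjusted p = 0.0934). The score of basement membrane genes was -0.027 to 0.044 and 0.054 to 0.132. The integrin subunit of hemidesmosomes Itgb4 had 0.32 ± 0.08 and nidogen Nid1 had 0.42 ± 0.13. Ligands of axon growth and guidance were higher as a list, with 27 of 32 members positive, a median of 0.07 and none passing over all genes or adjusted over the list alone (adjusted p = 0.000609, and adjusted p = 0.303 with an estimated correlation). The score of these ligands was -0.04 to 0.018 in OPA1+/+ and 0.057 to 0.112 in OPA1+/-, and so moved with that of the endothelium markers. Its members Vegfa, a growth factor of vessels and nerves, and Sema3f, a repulsive axon guidance cue, had 0.63 ± 0.19 and 0.12 ± 0.04, and neither passed.

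Lists of interferon response, heat shock, conjunctival, lymphocyte and lens genes also differed at 3 months, with no member past the threshold. Interferon response genes were lower (29 of 33 negative, median -0.17, adjusted p = 4.32e-05, and adjusted p = 0.855 with an estimated correlation). Heat shock and folding genes were lower too (20 of 25 negative, median -0.09, adjusted p = 0.000744, and adjusted p = 0.626 with an estimated correlation). Conjunctiva and goblet cell markers were lower (8 of 9 negative, median -0.26, adjusted p = 0.0278, and adjusted p = 0.573 with an estimated correlation). T and NK lymphocyte markers were lower (6 of 6 negative, median -0.44, adjusted p = 0.0446, and adjusted p = 0.81 with an estimated correlation). Lens genes were higher (10 of 10 positive, median 1.27, adjusted p = 0.00852, and adjusted p = 0.573 with an estimated correlation). The lens score was 2.4 in OPA1+/- replicate 4, where the lens crystallin Cryaa reached 56.5 CPM, and at most 1.19 in the other 14 libraries. In none of these lists did a member pass when adjusted over the list alone. The interferon score was -0.781 and -0.641 in OPA1+/- replicates 1 and 3, and 0.266 and 0.334 in replicates 2 and 4, above the -0.114 to 0.235 of OPA1+/+. Its call was lost without OPA1+/- replicate 1 (adjusted p = 0.287) or 3 (0.106). The heat shock call was lost without OPA1+/+ replicate 3 (adjusted p = 0.239), whose score was 0.175 against 0.036 to 0.046 in the rest of its group. The conjunctiva call was lost without OPA1+/+ replicate 2 (adjusted p = 0.0941) or 3 (0.0538) or OPA1+/- replicate 1 (0.0772) or 4 (0.183). The lens call was lost without OPA1+/+ replicate 2 (0.0632) or 3 (0.059) or OPA1+/- replicate 4 (0.179). The lymphocyte call was lost in 9 of 15 such fits (adjusted p up to 0.263).

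Of 15770 genes tested at 3 months, 1424 had an unadjusted p under 0.05, 43 passed with DESeq2 and 5 with limma voom. The count of 1 became 0 without OPA1+/+ replicate 1 or OPA1+/- replicate 2, 3 or 4, became 2 without OPA1+/- replicate 4 at 6 months, 9 without OPA1+/+ replicate 1 at 6 months, and 18 without OPA1+/+ replicate 4 at 3 months.

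The same question at 6 months gave 51 genes, 25 higher and 26 lower in OPA1+/-. Genes of the circadian clock were among those that rose. Ciart, a repressor of the clock, was at 5.82 ± 1.81 CPM in OPA1+/+ (n = 3) and 14.7 ± 2.72 CPM in OPA1+/- (n = 4), a log2 fold change of 1.34 ± 0.26 (adjusted p = 0.0426). The clock repressor Bhlhe41 rose by 1.07 ± 0.18 on the log2 scale (adjusted p = 0.0261), and the clock-controlled transcription factors Dbp (0.85 ± 0.12, adjusted p = 0.0155) and Tef (0.59 ± 0.07, adjusted p = 0.000623) rose with it. Of 19 clock genes tested, 6 rose, none fell and 13 did not pass. Nr1d2, a nuclear receptor that represses Arntl, and the period gene Per3 were also among those that rose (0.47 ± 0.07 and 0.34 ± 0.06). Adjusted over the list alone, 8 rose and 3 fell. The list had adjusted p = 6.16e-07, and adjusted p = 0.0667 with an estimated correlation. The 3 OPA1+/+ libraries of 6 months stood apart from the other 12 in the clock activator Arntl, at 39.5 to 54.3 CPM against 10.2 to 26.6 CPM, a gene chosen after its values were seen.

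**Figure D2:**
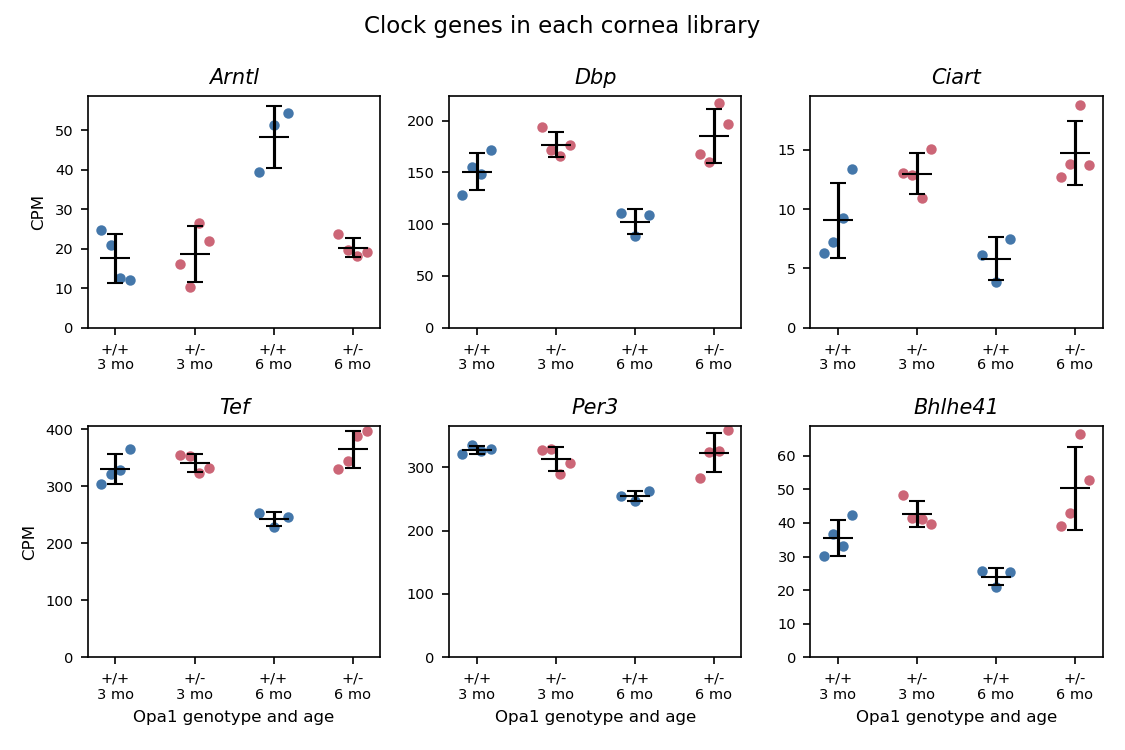
CPM (vertical axes, linear from 0) of 6 clock genes in each library, by genotype and age (horizontal axes). Points are libraries, horizontal marks are means and bars are SD, and in the OPA1+/+ libraries of 6 months Arntl lies at 39.5 to 54.3 CPM, above all others, and Dbp at 88.5 to 110 CPM, below all others.

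Of 35 cell cycle genes tested at 6 months, 2 fell, none rose and 33 did not pass, and 22 fell and 5 rose when adjusted over the list alone. The list had a median log2 fold change of -0.55 and adjusted p = 5.58e-07, and adjusted p = 0.726 with an estimated correlation. Kif11 was at 32.9 ± 3.6 CPM in OPA1+/+ and 19.9 ± 1.85 CPM in OPA1+/- (log2 fold change -0.73 ± 0.11, adjusted p = 0.0119), and Nusap1 had -0.78 ± 0.15 (adjusted p = 0.0402). Outside the list, named by their fold changes, the genes that fell included the kinesins Kif2c (-0.77 ± 0.15), Kif14 (-0.77 ± 0.14) and Kif22 (-0.73 ± 0.13), the spindle proteins Spag5 (-0.69 ± 0.12) and Troap (-0.93 ± 0.17), and the kinetochore protein Spc25 (-0.68 ± 0.12). The kinase Bub1b of the spindle checkpoint had -0.63 ± 0.14 and did not pass (adjusted p = 0.0599).

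Other genes that changed at 6 months included the translational regulator Cpeb1 (1.28 ± 0.17, adjusted p = 0.00228), the lipoprotein receptor Vldlr (0.98 ± 0.16, adjusted p = 0.0155), the ciliary protein Cys1 (0.85 ± 0.17, adjusted p = 0.0307), the tetraspanin Tspan4 (0.84 ± 0.16, adjusted p = 0.0288), the growth factor Bmp7 (0.70 ± 0.14, adjusted p = 0.0307) and the glutaredoxin Glrx (0.61 ± 0.11, adjusted p = 0.0155), which rose. The adhesion molecule Clmp (-1.03 ± 0.18, adjusted p = 0.0157) and the dynamin Dnm3 (-0.65 ± 0.13, adjusted p = 0.0307) fell. Of 25 immediate early genes tested, 3 fell, both over all genes and adjusted over the list alone: Btg2 (-0.51 ± 0.09), Jun (-0.35 ± 0.07) and Jund (-0.32 ± 0.07). The other 22 did not pass, and the list had adjusted p = 0.000439, and adjusted p = 0.726 with an estimated correlation. Its call was lost without OPA1+/+ replicate 2 (adjusted p = 0.102).

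The list of mitochondrial stress and the integrated stress response was higher at 6 months, with 25 of 33 members positive and a median of 0.18. Of its members 1 rose (Vldlr), none fell and 32 did not pass, and 3 were higher when adjusted over the list alone (adjusted p = 3.6e-05, and adjusted p = 0.726 with an estimated correlation). The scores overlapped: OPA1+/- replicate 4 had -0.133 and the other 3 had 0.11 to 0.288, and OPA1+/+ had 0.008, -0.254 and -0.096. Atf5, a transcription factor of the mitochondrial unfolded protein response, had 0.49 ± 0.12, and the mitochondrial chaperones Hspd1 and Hspa9 had 0.24 ± 0.07 and 0.19 ± 0.06, and none of the 3 passed. Interferon response genes were higher at this age (31 of 33 positive, median 0.19, adjusted p = 0.00377, and adjusted p = 0.975 with an estimated correlation) and cytokine genes were lower (13 of 17 negative, median -0.20, adjusted p = 0.0465, and adjusted p = 0.94 with an estimated correlation), with no member of either past the threshold, over all genes or adjusted over the list alone. The interferon call was lost without OPA1+/+ replicate 3 (adjusted p = 0.262) or OPA1+/- replicate 3 (0.263), and the cytokine call in 7 of 15 fits that left out 1 library (up to 0.237).

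Of the genes named for 6 months, Opa1 and Tef kept their calls whichever library was left out, and Ciart lost its call in 11 of 15 such fits, Nusap1 in 8, Kif2c in 7 and each of the others in 1 to 6. The count at 6 months depended on single libraries: it was 2 without OPA1+/+ replicate 2, 18 without OPA1+/+ replicate 1, 12 without OPA1+/- replicate 3, 22 without OPA1+/- replicate 2, and 86 without OPA1+/+ replicate 4 of 3 months. It was 191 with only the 2 groups compared, 181 with DESeq2, 140 with no filter on low counts and 105 with limma voom. It was 25 with the Y-linked covariate, 14 without the 2 libraries with retina transcripts and 0 with the clock covariates. With the clock covariates 69 of the 73 gene calls taken up for the text, over all comparisons, were lost and 3 changed sign. For clock genes this follows in part from the covariates, which were computed from these genes.

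Averaged over both ages, 125 genes changed with genotype, 63 higher and 62 lower in OPA1+/-. Kif11 fell (log2 fold change -0.58 ± 0.08, adjusted p = 0.00409), as did Nusap1 (-0.63 ± 0.10), the ubiquitin-conjugating enzyme of mitotic exit Ube2c (-0.60 ± 0.12), Dlgap5 of the spindle (-0.54 ± 0.08), the cyclin Ccnf (-0.52 ± 0.10) and the mitotic kinase Cdk1 (-0.49 ± 0.10). Of 35 cell cycle genes tested, 9 fell, none rose and 26 did not pass, and 22 fell and 1 rose when adjusted over the list alone. The list had adjusted p = 2.52e-09, and adjusted p = 0.564 with an estimated correlation. Kif11 was at 18.1 to 22.5 CPM in the 8 OPA1+/- libraries and at 22.8 to 36.5 CPM in the 7 OPA1+/+ libraries. Ccnd2, a cyclin of the G1 phase, rose in the averaged comparison (log2 fold change 0.66 ± 0.12, adjusted p = 0.0309). At 3 months it was at 261 ± 45.4 CPM in OPA1+/+ and 354 ± 49.9 CPM in OPA1+/-, with overlapping libraries, and did not pass. At 6 months it was at 244 ± 15.5 and 447 ± 88.3 CPM.

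Of 20 glycolysis genes tested in the averaged comparison, 2 rose, none fell and 18 did not pass, and 5 rose when adjusted over the list alone (adjusted p = 3.74e-06, and adjusted p = 0.564 with an estimated correlation). The list was called at 3 months and not at 6 months (adjusted p = 0.0759), where the score of OPA1+/- replicate 4 was -0.111, below the -0.073 to -0.032 of OPA1+/+. The interaction of this list was not called (adjusted p = 0.0869). Slc16a3 rose by 0.87 ± 0.19 on the log2 scale (adjusted p = 0.038), at 2.83 to 3.6 CPM in OPA1+/- against 0.8 to 1.7 CPM in OPA1+/+ at 3 months. At 6 months OPA1+/- libraries reached 3.46 CPM against 1.71 to 2.16 CPM in OPA1+/+, and OPA1+/- replicate 4 lay below every OPA1+/+ library. Pfkfb3, which makes the allosteric activator of phosphofructokinase, rose by 0.21 ± 0.04 (adjusted p = 0.027). Ndufa4l2, a subunit related to mitochondrial complex IV that hypoxia induces, rose by 0.69 ± 0.15 in the averaged comparison (adjusted p = 0.0309). At 3 months it was at 1.21 ± 0.30 CPM in OPA1+/+ and 2.03 ± 0.25 CPM in OPA1+/-, and did not pass. At 6 months it was at 1.87 ± 0.13 and 2.89 ± 0.32 CPM. Cpeb1 (0.81 ± 0.12), Nxph4, a neurexophilin (0.82 ± 0.17), Ndst3, an enzyme of heparan sulfate synthesis (0.70 ± 0.14), Ttc39a (0.72 ± 0.16) and Vldlr (0.59 ± 0.11) rose, and Clmp (-0.59 ± 0.12) fell. Of 19 clock genes 4 rose (Ciart, Bhlhe41, Dbp and Tef), none fell and 15 did not pass, and 10 rose and 3 fell when adjusted over the list alone (adjusted p = 0.000129, and adjusted p = 0.284 with an estimated correlation).

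**Figure D3:**
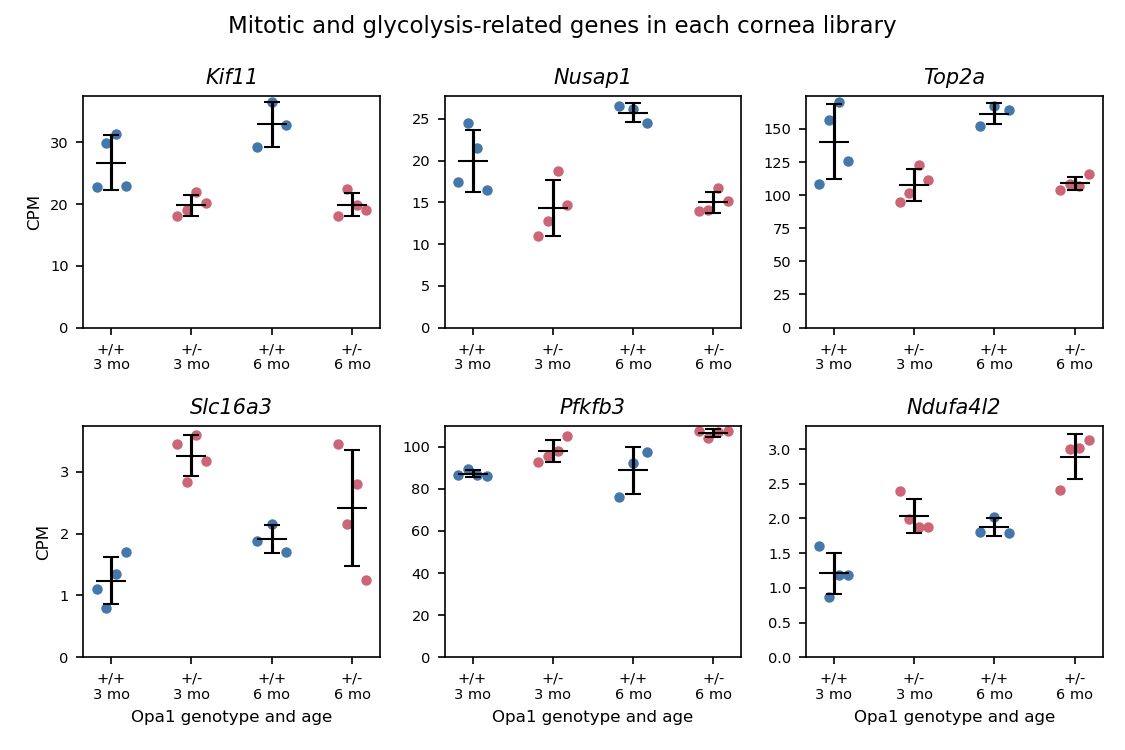
CPM (vertical axes, linear from 0) of 3 mitotic genes and 3 genes of glycolytic or hypoxic metabolism in each library, by genotype and age (horizontal axes). Points are libraries, horizontal marks are means and bars are SD, and Kif11 lies at 18.1 to 22.5 CPM in OPA1+/- and at 22.8 to 36.5 CPM in OPA1+/+.

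The share of counts from mitochondrial genes was 2.77% to 3.10% in the 7 OPA1+/+ libraries and 2.50% to 2.74% in the 8 OPA1+/- libraries, a comparison chosen after the values were seen and not tested. Most of it was ribosomal RNA of mitochondria, at 2.30% to 2.64% and 2.10% to 2.31%, in libraries from which ribosomal RNA had been depleted. Averaged over both ages, the large ribosomal RNA of mitochondria mt-Rnr2, also chosen after its values were seen, fell by 0.19 ± 0.03 on the log2 scale (adjusted p = 0.0141). Without the 2 libraries with retina transcripts mt-Rnr2 was not called (adjusted p = 0.0651). The small ribosomal RNA mt-Rnr1 had -0.06 ± 0.04 (adjusted p = 0.6). Of 26 genes of mitochondrial fusion, fission and cristae tested, Opa1 fell and 25 did not pass, and adjusted over the list alone Opa1 was again the 1 call (median 0.01, adjusted p = 0.95). None of 37 nuclear genes of complex I (adjusted p = 0.638), 14 of ATP synthase (adjusted p = 0.0669), 47 of the mitochondrial ribosome (adjusted p = 0.459) or 23 of mitophagy and autophagy (adjusted p = 0.888) passed over all genes. Adjusted over the list alone, 1 mitophagy gene was higher, and the receptor Bnip3 had 0.69 ± 0.18 (adjusted p = 0.0759 over all genes). Nuclear genes of complexes II to IV were higher as a list (18 of 25 positive, median 0.04, adjusted p = 0.0492, and adjusted p = 0.739 with an estimated correlation). The 7 measured mRNAs of mitochondrial DNA were lower (6 of 7 negative, median -0.06, adjusted p = 0.0492, and adjusted p = 0.739 with an estimated correlation). No member passed over all genes, and 2 of the mitochondrial mRNAs were lower when adjusted over the list alone. Leaving out 1 library ended the call of the mitochondrial mRNAs in 11 of 15 fits (adjusted p up to 0.133) and that of complexes II to IV in 9 of 15 (up to 0.158). The mitochondrial mRNA score was -0.304 in OPA1+/+ replicate 4 of 3 months and 0.085 to 0.117 in the rest of its group. Without that library the list had adjusted p = 3.92e-05 averaged and 2.33e-06 at 3 months, where it was otherwise not called (0.0934). The complex IV mRNA mt-Co1 had -0.22 ± 0.06 (adjusted p = 0.0828, and 0.000957 without that library). The other 6 of the 13 mitochondrial mRNAs had at most 3 counts over all libraries, and mt-Co2, mt-Co3, mt-Atp8 and mt-Nd4l were listed at 0.

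Of the stress response list, 1 gene rose (Vldlr), none fell and 32 did not pass in the averaged comparison, and 4 rose when adjusted over the list alone (adjusted p = 0.00023, and adjusted p = 0.593 with an estimated correlation). The amino acid transporter Slc7a1 had 0.30 ± 0.07 (adjusted p = 0.0594). Cholesterol synthesis genes were higher (18 of 23 positive, median 0.06, 1 higher when adjusted over the list alone, adjusted p = 0.0333, and adjusted p = 0.81 with an estimated correlation). Cytokine genes were lower (12 of 17 negative, median -0.09, 1 higher when adjusted over the list alone, adjusted p = 0.0492, and adjusted p = 0.78 with an estimated correlation). Markers of conjunctiva (7 of 9 negative, median -0.32, adjusted p = 0.0203, and adjusted p = 0.585 with an estimated correlation) and of T and NK lymphocytes (6 of 6 negative, median -0.34, 1 lower when adjusted over the list alone, adjusted p = 0.0492, and adjusted p = 0.695 with an estimated correlation) were lower too. No member of these 4 lists passed over all genes. Leaving out 1 library ended the cholesterol synthesis call in 8 of 15 fits (adjusted p up to 0.368), the cytokine call in 10 (up to 0.244) and the lymphocyte call in 10 (up to 0.245). The conjunctiva call was lost without OPA1+/+ replicate 1 (0.0845) or OPA1+/- replicate 1 (0.0604) of 6 months.

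Of 34 sensory nerve genes, 11 were tested and none passed (median -0.11, adjusted p = 0.95). The score of this list was highest in the 2 libraries with retina transcripts (0.477 and 0.589, against -0.498 to 0.136). Its members Syt1 and Snap25 were at 5.27 and 2.58 CPM in 1 of them and 5.88 and 4.75 CPM in the other, and at most at 0.77 and 0.93 CPM elsewhere. The cold receptor Trpm8 had 11 counts over all 15 libraries, the heat receptor Trpv1 28, the neuropeptide gene Calca 1, and Calcb, Scn10a, Scn11a, Mrgprd and Gal 0. Differences in these genes were therefore not detectable in these libraries, and the reason for the low counts was not tested. The neurotrophin receptor Ntrk2 was at 66.5 to 87.9 CPM in group means and had 0.27 ± 0.10 in the averaged comparison (adjusted p = 0.258). Of 13 Schwann cell genes none passed over all genes, 2 were higher and 1 lower when adjusted over the list alone, and the neuregulin receptor Erbb3 had -0.16 ± 0.04 (adjusted p = 0.0563; list adjusted p = 0.95). Of 32 axon growth and guidance ligands none passed over all genes and 2 were higher when adjusted over the list alone (median 0.03, list adjusted p = 0.0669). Vegfa had 0.63 ± 0.14 (adjusted p = 0.0563) and the ephrin Efnb2 0.15 ± 0.04 (adjusted p = 0.0653). None of 29 corneal epithelium genes passed, over all genes or adjusted over the list alone (median -0.04, list adjusted p = 0.342).

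Of the genes named for the averaged comparison, Opa1, mt-Rnr2, Kif11, Dlgap5, Cpeb1, Tef and Dbp kept their calls whichever library was left out. Slc16a3, Ube2c and Clmp lost theirs in 11 of 15 such fits, Ccnd2 and Cdk1 in 10, Nxph4, Ttc39a and Ndufa4l2 in 9 and the others in 1 to 6. The averaged count of 125 was 314 with DESeq2, 244 with limma voom, 16 with the Y-linked covariate, 19 without the 2 libraries with retina transcripts and 0 with the clock covariates. Left-out libraries moved it to 36, 79 or 53 (OPA1+/- replicate 1, 2 or 4 of 3 months), 50, 81 or 26 (OPA1+/- replicate 1, 2 or 3 of 6 months), 51, 195 or 238 (OPA1+/+ replicate 2, 3 or 4 of 3 months) and 44 or 16 (OPA1+/+ replicate 1 or 2 of 6 months).

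Across the 15770 tested genes, the genotype fold changes at 3 and 6 months had a Pearson r of 0.0644 and a Spearman rho of 0.122, and r was 0.252 among 9286 genes with a mean of at least 10 CPM. The 2 comparisons share no library, and genes are not independent replicates. Opa1 was the 1 gene called at both ages, where independent lists would share 0.00165 fallers. Of the 50 other genes called at 6 months, 38 had the same sign at 3 months, and 17 of these also had an unadjusted p under 0.05 there.

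Age in OPA1+/+ corneas was compared between 3 libraries of 6 months and 4 of 3 months, and 8 genes changed, 5 higher and 3 lower at 6 months. Cdkn1a, the p21 cell cycle inhibitor (0.37 ± 0.07, adjusted p = 0.0406), and Egln3, a prolyl hydroxylase that senses oxygen (0.34 ± 0.06, adjusted p = 0.0429), rose. Csmd2, a membrane protein with complement-type domains, rose from 2.35 ± 0.17 to 5.0 ± 0.83 CPM (1.08 ± 0.18, adjusted p = 0.0343), and Bzw1, a regulator of translation, by 0.26 ± 0.05 (adjusted p = 0.0429). Chsy3, an enzyme of chondroitin sulfate synthesis, fell (-0.74 ± 0.12, adjusted p = 0.0343), as did the clock genes Tef (-0.44 ± 0.07, adjusted p = 0.0259) and Per3 (-0.37 ± 0.06, adjusted p = 0.0343). Of 19 clock genes 2 fell, none rose and 17 did not pass, and 2 rose and 7 fell when adjusted over the list alone (adjusted p = 0.0151, and adjusted p = 0.38 with an estimated correlation). These clock differences rest on the same 3 OPA1+/+ libraries of 6 months that stood apart in the genotype comparison. Age therefore cannot be told apart from a different time of harvest of these libraries. The clock call was lost without OPA1+/+ replicate 2 of 6 months (adjusted p = 0.0835), and each gene call named here was lost in 3 (Tef) to 12 (Bzw1) of 15 fits that left out 1 library.

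In OPA1+/+ corneas, matrix and stromal genes were lower at 6 months as lists. Of 40 genes of extracellular matrix and collagens, 33 had negative fold changes (median -0.19), none passed over all genes and 7 fell when adjusted over the list alone (adjusted p = 6.3e-09, and adjusted p = 0.38 with an estimated correlation). The scores of this list overlapped, at 0.115, -0.084 and -0.309 (replicate 3) at 6 months and 0.009 to 0.225 at 3 months. Without replicate 3 of 6 months the list had adjusted p = 0.00231. The collagen Col16a1 had -0.43 ± 0.09 and the collagen chaperone Serpinh1 -0.34 ± 0.08. Of 23 keratocyte genes, 22 were negative (median -0.24), none passed over all genes and 2 fell when adjusted over the list alone (adjusted p = 1.1e-07, and adjusted p = 0.38 with an estimated correlation). Angptl7, a secreted factor of the corneal stroma, was at 331 ± 74 CPM at 3 months and 172 ± 48.9 CPM at 6 months (-0.95 ± 0.23, adjusted p = 0.161). Immediate early genes were higher (23 of 25 positive, median 0.28, none over all genes and 5 adjusted over the list alone, adjusted p = 2.96e-08, and adjusted p = 0.337 with an estimated correlation). Heat shock and folding genes were lower (18 of 25 negative, median -0.11, none over all genes and 2 adjusted over the list alone, adjusted p = 0.000379, and adjusted p = 0.477 with an estimated correlation), a call lost without OPA1+/+ replicate 3 of 3 months (adjusted p = 0.0519). The count of 8 was 117 with DESeq2, 19 with limma voom, 0 with the clock covariates and 144 without the 2 libraries with retina transcripts. Leaving out 1 library gave 168 (OPA1+/+ replicate 1 of 6 months), 0 (OPA1+/+ replicate 2 or 3 of 6 months, or replicate 2 of 3 months), 13 (OPA1+/+ replicate 1 of 3 months), 34 or 5 (OPA1+/- replicate 2 or 1 of 3 months) and 2, 3 or 5 (OPA1+/- replicate 2, 3 or 4 of 6 months).

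Age in OPA1+/- corneas changed 13 genes, 3 higher and 10 lower at 6 months. The matrix metalloproteinases Mmp2 (-0.63 ± 0.11), Mmp14 (-0.29 ± 0.05) and Mmp15 (-0.46 ± 0.08) fell, each with adjusted p = 0.0427. The collagen Col11a1 fell from 7.48 ± 1.26 to 3.76 ± 0.55 CPM (-0.998 ± 0.165, adjusted p = 0.0427), and Col16a1 had -0.44 ± 0.08 (adjusted p = 0.0455). The Wnt ligand Wnt11 (-0.73 ± 0.13), the Wnt inhibitor Dkk1 (-0.71 ± 0.13), the latent TGF-beta binding protein Ltbp1 (-0.50 ± 0.09) and the secreted proteins Olfml3 (-0.57 ± 0.10) and Srpx2 (-0.47 ± 0.09) fell too. Vldlr (0.83 ± 0.15, adjusted p = 0.0427) and Id4, an inhibitor of differentiation factors (0.48 ± 0.09, adjusted p = 0.0455), rose. Each gene named here lost its call in 8 to 11 of 15 fits that left out 1 library.

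Of 40 genes of extracellular matrix and collagens tested in OPA1+/-, 3 fell, none rose and 37 did not pass, and 18 fell when adjusted over the list alone (median -0.25, adjusted p = 1.21e-17, and adjusted p = 0.207 with an estimated correlation). The transcript ENSMUSG00000119584, chosen after its values were seen and not tested as a covariate, held 0.084% to 0.167% of counts at 3 months and 0.301% to 0.667% at 6 months in OPA1+/-. Basement membrane genes were lower, with 24 of 25 members negative, a median of -0.14, none past the threshold over all genes and 3 falling when adjusted over the list alone (adjusted p = 1.61e-08, and adjusted p = 0.0101 with an estimated correlation). This was the 1 list call of the 50 over the 6 comparisons that held with an estimated correlation. Its members included the laminins Lama2 (-0.48 ± 0.11), Lama5 (-0.22 ± 0.06) and Lamc1 (-0.22 ± 0.06). Of 23 keratocyte genes, 19 were negative (median -0.28), none passed over all genes and 10 fell when adjusted over the list alone (adjusted p = 2.19e-09, and adjusted p = 0.207 with an estimated correlation). Axon growth and guidance ligands were lower (25 of 32 negative, median -0.11, adjusted p = 0.00302, and adjusted p = 0.207 with an estimated correlation), with none past the threshold over all genes or adjusted over the list alone.

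Interferon response genes were higher at 6 months in OPA1+/- (32 of 33 positive, median 0.30, adjusted p = 1.95e-10, and adjusted p = 0.546 with an estimated correlation). Their score at 3 months was -0.781 and -0.641 in replicates 1 and 3, and 0.266 and 0.334 in replicates 2 and 4, above 3 of the 4 libraries of 6 months (-0.134, 0.083 and 0.232). The T and NK lymphocyte score was -0.518 and -0.614 in replicates 1 and 3 and 0.417 and 0.181 in replicates 2 and 4. Genes of cytosolic nucleic acid sensing were higher (9 of 11 positive, median 0.17, adjusted p = 0.0308, and adjusted p = 0.605 with an estimated correlation). Clock genes (17 of 19 positive, median 0.08, adjusted p = 0.0197, and adjusted p = 0.278 with an estimated correlation) and the stress response list (24 of 33 positive, median 0.08, adjusted p = 0.0387, and adjusted p = 0.642 with an estimated correlation) were higher. Lists of myofibroblasts (8 of 9 negative, median -0.19, adjusted p = 0.0358, and adjusted p = 0.546 with an estimated correlation), vessels (7 of 9 negative, median -0.44, adjusted p = 0.00823, and adjusted p = 0.207 with an estimated correlation) and lens (9 of 10 negative, median -3.03, adjusted p = 0.000127, and adjusted p = 0.207 with an estimated correlation) were lower. Vldlr was the 1 member of these 7 lists past the threshold over all genes. Adjusted over the list alone, 1 stress response gene rose, and 1 myofibroblast, 2 vessel and 8 lens genes fell. The lens scores of OPA1+/- replicates 1 to 4 at 3 months were 0.862, -1.054, 1.187 and 2.4, against -0.893 to -0.027 at 6 months. Replicate 2 thus lay below every OPA1+/- library of 6 months, and in replicate 4 the lens crystallin Cryaa was at 56.5 CPM. Leaving out 1 library ended the calls of the stress response in 6 of 15 fits (adjusted p up to 0.281), myofibroblasts in 4 (up to 0.127), nucleic acid sensing in 3 (up to 0.257), clock genes in 2 (up to 0.101) and vessels in 1 (0.0855, without OPA1+/- replicate 1 of 6 months). The count of 13 was 70 with DESeq2, 32 with limma voom, 4 with either the Y-linked or the clock covariates and 5 without the 2 libraries with retina transcripts. It was 1 to 4 without any 1 of the OPA1+/- libraries, 1 without OPA1+/+ replicate 1 of 3 months, 23 or 21 without OPA1+/+ replicate 3 or 4 of 3 months and 8 without OPA1+/+ replicate 2 of 6 months.

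The age effects in the 2 genotypes had a Pearson r of 0.0588 and a Spearman rho of 0.139 across genes, and 1 gene was called in both. It has no symbol in the table used here (ENSMUSG00002076161, chromosome 9, bases 78082585 to 78082915, GRCm39, 331 bases) and was chosen after its values were seen. It held 2947 to 3685 raw CPM in the libraries of 3 months and 4117 to 4481 raw CPM in those of 6 months.

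Whether the genotype effect differed between ages was tested by the interaction, and no gene passed in edgeR, where 1090 had an unadjusted p under 0.05. DESeq2 gave 21 genes and limma voom 0. The smallest adjusted p was 0.112, shared by Tef (0.54 ± 0.09), the clock receptor Nr1d2 (0.53 ± 0.10), the transcription factors Jund (-0.49 ± 0.09), Jun (-0.50 ± 0.10) and Srf (-0.57 ± 0.11), the mechanosensitive channel Piezo1 (-0.29 ± 0.06) and the adhesion receptor Adgrf4 (-0.73 ± 0.13). Clock genes as a list had a more positive genotype effect at 6 months (14 of 19 positive, median 0.35, none over all genes, 6 up and 3 down adjusted over the list alone, adjusted p = 8.52e-05, and adjusted p = 0.253 with an estimated correlation). Immediate early genes had a more negative one (23 of 25 negative, median -0.19, none over all genes, 3 down adjusted over the list alone, adjusted p = 9.55e-06, and adjusted p = 0.443 with an estimated correlation). For both lists, genotype at 6 months, age in OPA1+/+ and the interaction share the OPA1+/+ libraries of 6 months, so the results are not independent. Time of harvest is not known for these libraries. Interferon response genes had a more positive genotype effect at 6 months (32 of 33 positive, median 0.37, none over all genes or adjusted over the list alone, adjusted p = 1.85e-08, and adjusted p = 0.994 with an estimated correlation). The count of 0 became 4 without OPA1+/- replicate 1 of 6 months, 10 without OPA1+/+ replicate 1 of 6 months and 9 without the 2 libraries with retina transcripts.

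RNA of neighbouring eye tissues varied between libraries. The score of the retina list was 2.32 in OPA1+/- replicate 4 of 3 months and 2.29 in OPA1+/+ replicate 1 of 6 months, and -0.84 to 0.21 in the other 13 libraries. These are the 2 libraries named above for retina transcripts. The conjunctiva and goblet cell score was 0.31 ± 0.15 in OPA1+/+ and -0.03 ± 0.23 in OPA1+/- at 3 months, and 0.01 ± 0.45 and -0.29 ± 0.21 at 6 months.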

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

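The tests of cell cycle genes with clock and conjunctiva covariates, of the clock list at 3 months and of the genes near Opa1 were chosen after the result was seen. The covariate fits and the fit without the 2 libraries with retina transcripts were also chosen after seeing the data. The harvest-time test on clock scores and the other splits of the samples were set out before their values were computed, though the called lists had been seen.

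As a list, cell cycle genes were lower in OPA1+/-, with a median log2 fold change over 35 genes of -0.408 ± 0.117 (jackknife SE) in a linear model without covariates. Not all genes of proliferation moved this way. The G1 cyclin Ccnd2 rose in the averaged comparison. Mcm5, a replicative helicase subunit chosen after its values were seen, was at 39.2 to 53.3 CPM in OPA1+/- at 6 months. In OPA1+/+ of that age it was at 28.6 to 33.8 CPM. The share of conjunctival tissue, a proliferating neighbour of the cornea, stays open. With the conjunctiva score as covariate the median was -0.365 ± 0.178, below 0 by just over 2 SE. By the rule, written after the result was seen, this counted against conjunctiva as the whole source. The value was also within 2 SE of that without the covariate. A score of marker genes measures tissue share imperfectly, so the covariate can leave part of such an effect. Time of harvest could not be told apart from genotype: with 2 clock components as covariates the median was -0.303 ± 0.249, within 2 SE of both 0 and the value without them, and 76.9% and 49.1% of the variance of these components lay between groups. The rule first written counted a value within 2 SE of 0 as going with harvest time, and it was read as open only after the value was seen. The OPA1 genotype itself stays open as the biological explanation.

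Clock genes differed between genotypes at 6 months. Over the 15 libraries, after subtracting group means, the score of the activators Arntl, Npas2 and Clock and the score of 9 output genes had a Pearson r of -0.676 (two-sided permutation p = 0.0167, Benjamini-Hochberg 0.0334) and a Spearman rho of -0.60 (permutation p = 0.0404, Benjamini-Hochberg 0.0404), and r was -0.554 without the 2 libraries farthest from the median of the activator score (OPA1+/+ replicates 1 and 4 of 3 months). It was 1 of 2 correlations computed. Harvest at different times of day would give this opposite movement within groups, and the labels give no time. The correlation cannot tell harvest time from genotype as the source of the difference between groups, since group means were subtracted. The OPA1 genotype stays open. The clock list had adjusted p = 0.533 (camera) between genotypes at 3 months. That list mixes activators and outputs, which moved oppositely, so a test in 1 direction can miss a shift. At 3 months the output score was -0.046 ± 0.101 (SD) in OPA1+/+ and 0.096 ± 0.032 in OPA1+/-, with overlapping libraries. The activator score was -0.168 ± 0.281 and -0.12 ± 0.157. The difference at 6 months cannot be told apart from a different harvest time of the 3 OPA1+/+ libraries.

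Genes near Opa1 differed between genotypes. Within 10 Mb to each side, 4 of 153 tested genes besides Opa1 were called in the averaged comparison, each near the threshold. St6gal1 (0.25 ± 0.06, adjusted p = 0.037), Lpp (0.20 ± 0.04, adjusted p = 0.0239) and Acap2 (0.14 ± 0.03, adjusted p = 0.0482) were higher. Fam43a (-0.27 ± 0.06, adjusted p = 0.0439) was lower. A share of 0.0411 of 12406 overlapping windows of as many genes elsewhere held as many calls (median 1, highest 5). This goes weakly with sequence linked to the Opa1 allele, since neighbouring windows share most of their genes and the test was chosen after the result. Such sequence could differ between the genotypes if the allele was made in another strain, and the labels do not settle it. An effect of OPA1 itself on these genes was not tested and stays open.

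Other splits of the samples into groups of the same sizes were counted for each comparison. For genotype at 6 months 1 of 35 splits, the real one, gave a count as large as 51, and the highest other count was 1. For genotype averaged over both ages it was 1 of 100 (highest other 17), and for age in OPA1+/- 1 of 35 (highest other 1). At 3 months 5 of 35 splits gave at least 1 gene, and OPA1+/+ replicates 1 and 2 with OPA1+/- replicates 3 and 4 against the rest gave 29. For age in OPA1+/+ 3 of 35 splits gave at least 8 genes, and replicates 1 and 2 of 3 months with replicates 1 and 2 of 6 months against the rest gave 87. For the interaction all 100 gave at least 0, with 61 as the highest other. The counts at 3 months and for age in OPA1+/+ were therefore not larger than other groupings gave.

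The interaction differed for 9 lists under camera's preset correlation and for none with an estimated correlation. Higher at 6 months than at 3 months were the genotype effects of interferon response (adjusted p = 1.85e-08), circadian clock (8.52e-05), heat shock and folding (0.0155) and mitochondrial stress genes (0.0303). Lower were those of immediate early genes (adjusted p = 9.55e-06), cytosolic ribosome (0.0152), axon growth and guidance ligands (0.0155), retina (0.0244) and lens genes (0.0412). Leaving out 1 library ended the calls of lens genes in 8 of 15 fits (adjusted p up to 0.31), mitochondrial stress in 5 (up to 0.292), heat shock (up to 0.299), cytosolic ribosome (up to 0.173) and retina (up to 0.928) in 4 each, and axon growth and guidance ligands in 2 (up to 0.15). Without the 2 libraries with retina transcripts the retina list turned to the opposite direction past the threshold (adjusted p = 0.0185).

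Single libraries lay far from the other 3 of their group in 12 of 239 groups of 4 tested by Dixon's criterion, where chance alone gives about 1 in 20, or 11.9. In OPA1+/+ at 3 months, Dcn was at 432 CPM in replicate 3 (others 517 to 533), Serpinh1 at 40.5 CPM in replicate 3 (45.1 to 45.6), Jund at 94 CPM in replicate 4 (81.7 to 83) and Sparc at 255 CPM in replicate 4 (237 to 240). In the same group the list score of mitochondrial mRNAs was -0.304 in replicate 4 (0.085 to 0.117) and that of basement membrane -0.027 in replicate 2 (0.035 to 0.044). In replicate 3 the scores of mitochondrial stress (0.122, others -0.124 to -0.116), heat shock (0.175, others 0.036 to 0.046) and T and NK lymphocyte genes (0.183, others 0.351 to 0.385) stood apart. In OPA1+/- the extracellular matrix score was 0.043 in replicate 1 of 3 months (0.116 to 0.123), and the retina score was 2.32 in replicate 4 of 3 months (-0.612 to -0.19) and 0.162 in replicate 4 of 6 months (-0.436 to -0.413).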

How the results depend on the processing

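The clock covariates, the conjunctiva covariate and the fit without the 2 libraries with retina transcripts were chosen after seeing the data. Counts are given in the order genotype at 3 months, at 6 months, averaged, age in OPA1+/+, age in OPA1+/- and interaction, against 1, 51, 125, 8, 13 and 0. With DESeq2 they were 43, 181, 314, 117, 70 and 21, with no filter on low counts 45, 140, 256, 105, 83 and 19, and with limma voom 5, 105, 244, 19, 32 and 0. With the Y-linked covariate they were 0, 25, 16, 7, 4 and 0, with the clock covariates 0, 0, 0, 0, 4 and 0, and without the 2 libraries with retina transcripts 0, 14, 19, 144, 5 and 9. A fold change of at least 1 on the log2 scale left 0, 4, 1, 1, 0 and 0. With only the 2 groups compared, the counts at 3 months, at 6 months and for age in OPA1+/+ and OPA1+/- were 0, 191, 2 and 33. DESeq2 size factors and the filter on a mean of 1 CPM kept every count within 1.5 times. The cause was not tested. Leaving out libraries or adding covariates leaves fewer residual degrees of freedom, but this alone does not order the averaged counts. The replicate block takes up more of them than the Y-linked covariate, and left 90 genes against 16. Leaving out OPA1+/+ replicate 4 of 3 months gave 238.

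With the replicate block the counts were 0, 48, 90, 0, 3 and 0, and Opa1 at 3 months had -0.411 (adjusted p = 0.0515). The replicate numbers do not pair the libraries: residual profiles of the 21 same-number pairs correlated at -0.213 to 0.419, with a mean of -0.005 against 0.002 in other pairs.

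Leaving out 1 library at a time gave 0 to 18, 2 to 86, 16 to 238, 0 to 168, 1 to 23 and 0 to 10 genes. Opa1 ranged from -0.485 to -0.361 at 3 months, from -0.559 to -0.488 at 6 months and from -0.51 to -0.446 averaged. Its age effect ranged from -0.012 to 0.056 in OPA1+/+ and from -0.139 to -0.022 in OPA1+/-, and its interaction from -0.171 to -0.051. The agreement of the genotype effects at both ages ranged from 0.003 to 0.135.

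Opa1 at 3 months was not called with the Y-linked covariate (-0.391), the clock covariates (-0.383), without the 2 libraries with retina transcripts (-0.413) or with only the 2 groups compared (-0.418). At 6 months and averaged, the clock covariates alone ended its call (-0.526, adjusted p = 1, and -0.455, adjusted p = 0.961). There the fold change stayed within 0.02 of its value without covariates, and 76.9% and 49.1% of the variance of the 2 components lay between groups. The cause of the lost calls was not tested.

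Directions reversed with the clock covariates for Ciart at 6 months (-0.159), Bhlhe41 at 6 months (-0.038) and averaged (-0.02). They also reversed for the lists of interferon response (adjusted p = 0.95) and cytokines (0.1) at 6 months, mitochondrial mRNAs (0.516) and cytokines (0.151) averaged, and clock genes with age in OPA1+/+ (0.96). Without the 2 libraries with retina transcripts the retina list reversed in the interaction (adjusted p = 0.0185). The covariates were computed from the clock list, so the values of Ciart, Bhlhe41 and that list follow from their construction. For the other lists the cause was not tested.

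Of 73 gene calls taken up for the text, 73 held with DESeq2 and with limma voom, 72 with DESeq2 size factors, 69 with no filter, 42 with the replicate block, 28 with the Y-linked covariate, 25 without the 2 libraries with retina transcripts and 1 with the clock covariates. The 113 list results compared included lists that were not called, which had no call to lose. Of the called lists, 49 lost their call with an estimated correlation and 1 kept it. With fry 47 lost it. Low counts limited the sensory nerve genes, of which 11 of 34 were tested, and the reason for the low counts was not tested.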

Other observations

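The tests of hypoxia-inducible factor targets and of interferon against lymphocyte scores were set out before their values were computed, but after the patterns that prompted them had been seen. The r without the 2 libraries farthest on both scores and the r without 1 group were added after the correlation was seen.

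A transcript without a symbol, ENSMUSG00000119584 (chromosome 17, bases 40157244 to 40159092), held 0.077% to 0.667% of the counts of a library. In OPA1+/- it held 0.084% to 0.167% at 3 months and 0.301% to 0.667% at 6 months, without overlap. In OPA1+/+ the ages overlapped (0.104% to 0.453% and 0.077% to 0.506%). Mcm5, a replicative helicase subunit chosen after its values were seen, was at 25.1 and 31.9 CPM in OPA1+/+ replicates 1 and 2 of 3 months and at 69.9 and 59.5 CPM in replicates 3 and 4. The OPA1+/- libraries of 3 months, at 41.5 to 58.8 CPM, lay within this range. At 6 months Mcm5 was at 39.2 to 53.3 CPM in OPA1+/- and 28.6 to 33.8 CPM in OPA1+/+, opposite in direction to the cell cycle list. The interferon score was -0.781 and -0.641 in OPA1+/- replicates 1 and 3 of 3 months. The first 2 principal components of all tested genes held 14.01% and 11.8% of the variance.

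A hypothesis was that the higher Slc16a3, Ndufa4l2, Pfkfb3 and glycolysis genes of OPA1+/- were part of a higher output of hypoxia-inducible factor target genes. A list of 34 other targets, 32 of them tested, had camera p = 0.0117 in the averaged comparison (p = 0.0489 with an estimated correlation), with a median log2 fold change of 0.04 and 21 positive members. Of these genes 1 rose over all genes, Narf, and 5 rose and 1 fell when adjusted over the list alone. Adjusted over the 3 genotype comparisons, camera gave adjusted p = 0.0176 averaged, adjusted p = 0.000411 at 3 months and adjusted p = 0.717 at 6 months. With an estimated correlation these were adjusted p = 0.0734, adjusted p = 0.0194 and adjusted p = 0.757. The values went with the hypothesis at 3 months under both, averaged under the preset correlation alone, and at 6 months under neither. Protein or oxygen levels were not measured.

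A hypothesis was that the interferon score of a library followed its content of T and NK lymphocytes. The T and NK score rests on genes with few reads, with Cd3e at 0.08 to 1.07 CPM and Cd5 at 0.55 to 1.52 CPM. Over the 15 libraries, after subtracting group means, Pearson r was 0.694 (two-sided permutation p = 0.0399, Benjamini-Hochberg 0.0399) and Spearman rho 0.721 (permutation p = 0.0382, Benjamini-Hochberg 0.0404). Without the 2 libraries farthest from the median of the T and NK score (OPA1+/+ replicate 3 and OPA1+/- replicate 1 of 6 months) r was 0.761, and without the 2 farthest on both scores (OPA1+/- replicate 1 of 3 months and OPA1+/+ replicate 3 of 6 months) it was 0.659. Without the 4 OPA1+/- libraries of 3 months r fell to 0.492, so the relation rests in part on that group. It was 1 of 2 correlations computed, and it does not say which of the scores led the other.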
